A study of Mus musculus with 60 samples.

How the data were processed

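Bulk RNA sequencing was done on pieces of mouse embryonic brain from 5 regions at 4 daily stages from E11.5 to E14.5. The regions were the ventral midbrain, its neighbours along the ventral side (forebrain and hindbrain), the dorsal midbrain and the alar plate. There were 3 libraries per region and stage, 60 in all, in 20 groups. Per the labels, the embryos carried a TH-GFP transgene, a fluorescent reporter that helped to find dopaminergic tissue under the stereomicroscope, and the ventral midbrain pieces took in floor plate and basal plate. Total RNA was isolated with RNeasy columns and made into Illumina TruSeq libraries, per the labels. The labels do not say whether the libraries of a group came from separate embryos, so p-values measure the spread between samples.

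The deposited values are RPKM, made by the authors per kilobase of the listed transcript length and per 1000000 reads assigned to the listed features. This unit was read from the values: the products of value and length sum to 1000000 in each library and are whole multiples of 1 step per library. Per the submitters' processing notes, reads were mapped with Bowtie (version not given) to mm10. The read counter, the annotation release, the filters and the strand of the libraries are not given in the sources used here. Per the sample descriptions, the libraries carry 5 name prefixes, read here as runs. All E13.5 libraries share 1 prefix. All E12.5 libraries carry E12dot5, which names the stage, so that they were 1 run is assumed. At E11.5 the dorsal midbrain was in another run than the other regions. At E14.5 the ventral and dorsal midbrain shared 1 run and the other regions were in another. Stage and run therefore cannot be told apart in a comparison of stages.

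All 60 columns were matched to their samples, and 24378 features were listed. Of these, 2 names were repeated (Mar-01 and Mar-02, symbols altered by a spreadsheet) and 1207 names carried a locus suffix; all were kept as listed. Whole reads were recovered by dividing by the step, and 100.0% of values were whole within 0.001 of a read. Library totals ran from 1.58 to 6.43 (in units of 1000000 reads) at E11.5, 8.67 to 13.1 at E12.5, 4.97 to 23.6 at E13.5 and 0.979 to 6.13 at E14.5. A feature with 0 reads could have had up to 3 reads, a floor per library of 0.466 to 1.90 RPM (reads per 1000000 assigned) at E11.5, 0.229 to 0.346 at E12.5, 0.127 to 0.603 at E13.5 and 0.489 to 3.06 at E14.5. These floors cover counting error only, and a group with 0 in all libraries is given as listed at 0. The mean correlation of a library with its group, across genes, was 0.892 to 0.983 at E11.5, 0.921 to 0.993 at E12.5, 0.976 to 0.994 at E13.5 and 0.961 to 0.977 at E14.5. Between replicates of a group the lowest chi-square per feature was 1.12 (ventral midbrain E14.5 replicates 3 and 4), where counting noise alone gives about 1, so these values do not show that this pair came from separate samples.

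The analysis had been planned for counts, with a written fallback for normalised values. The deposited unit was normalised, so the fallback was used: limma 3.58.1 with a mean-variance trend on log2(RPKM + 1) in R 4.3.3. Genes were tested when their mean was at least 1 RPKM in any group of the fit. They were called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1, so "higher" and "lower" refer to genes past both thresholds. The pseudocount of 1 understates the fold change of genes with low values. The ventral midbrain was compared with the mean of the 4 other regions within each stage (15 libraries per fit), and with each other region averaged over the 4 stages (60 libraries in 1 fit). E14.5 was compared with E11.5 in the 12 ventral midbrain libraries. The last comparison set this change against the mean change in the 4 other regions (30 libraries). The comparisons, thresholds, gene lists and rule for named genes were set before the data were examined.

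Named genes are Th, Nr4a2, Pitx3, Slc6a3, Lmx1a, Lmx1b, Foxa2 and En1 (8 core genes) in each comparison, and up to 8 genes with the largest change in each direction among called genes with a mean of at least 5 RPKM. At a single stage, the 3 ventral midbrain libraries also had to lie all above or all below each library of the other regions. In the comparison of stages, the libraries of 1 stage had to lie beyond those of the other, and in averages over stages the difference had the same sign at all 4 stages. From each gene list discussed, up to 4 members with the smallest adjusted p are named. Predicted genes without a symbol were passed over. Some genes that the rule selects are not reported here, and no other gene takes their place; list counts and tallies include them. Gene positions are from GENCODE vM21 on the same build.

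The 28 lists (565 entries) cover the floor plate, dopaminergic, serotonergic, motor, GABAergic and glutamatergic neurons, general neuronal genes, radial glia, the cell cycle, canonical Wnt, Wnt planar polarity, hedgehog, Notch, retinoic acid and BMP/TGF-beta signalling, axon guidance, the extracellular matrix and dorsal, hindbrain and forebrain position. They also cover erythroid, endothelial, mesenchymal, microglial, oligodendrocyte, choroid plexus and pituitary markers and stress genes. Lists share members: 10 of the 20 floor plate genes, 5 of the 23 dopaminergic and 3 of the 8 serotonergic genes are in another list. Lists with at least 5 measured genes were tested with limma's camera with the correlation between genes estimated, adjusted over the lists of a comparison. Beside it stand the members called over all genes tested and adjusted over the list alone. With a preset correlation of 0.01 as the alternative, 88 of 270 tests passed against 19 with the estimated correlation.

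The alternatives were median centring, no filter, a pseudocount of 0.1, no fold minimum, a block for the replicate number, leaving out each library in turn, all 60 libraries in 1 fit, and sets of regions or stages that share a run. Alternatives added after seeing the data were limma with voom weights on the recovered reads, leaving out 6 libraries that stood apart from their groups, and leaving out E11.5. The 6 libraries were ventral midbrain E11.5 replicate 4, alar plate E11.5 replicate 4, ventral forebrain E11.5 replicates 4 and 6, alar plate E12.5 replicate 3 and ventral forebrain E12.5 replicate 1. No cutoff on the mean correlation with the group defines them. Alar plate E11.5 replicate 2 (0.923) and ventral hindbrain E11.5 replicate 2 (0.954) stayed in, while ventral midbrain E11.5 replicate 4 was at 0.958. The fits were tested on simulated data with 200 changed genes per draw and a spread pooled over all groups. The changed genes were drawn from those with a mean of at least 2 RPKM over all 60 libraries. Recovery of genes below that mean was not tested. At a log2 change of 1.5 and 3 on that data, 84.7% and 99.3% were recovered at E11.5, 90.3% and 99% at E12.5, 88.3% and 98.7% at E13.5 and 78% and 98% at E14.5. In the real data the median residual SD on the log2 scale was 0.242, 0.206, 0.135 and 0.206 from E11.5 to E14.5. The pooled spread leaves out these differences, so the shares for E11.5 may be too high. False calls per draw were 1 to 10 in the comparisons within a stage and across stages. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading and plotting.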

Results

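The series asks what sets the midbrain dopaminergic niche apart from its neighbours while its neurons are born. Values are RPKM as mean ± SD of 3 libraries, and changes are log2 fold changes ± standard error with limma's adjusted p. These changes are understated for genes with low values. The labels do not say whether libraries came from separate embryos, so p-values measure the spread between samples.

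The 8 core genes lie on 5 chromosomes of the mm10 build. Th, for the rate-limiting enzyme of dopamine synthesis, spans 142892752 to 142931128 on chromosome 7 (minus strand). Nr4a2 (57106830 to 57124003, minus), Lmx1b (33560965 to 33640511, minus) and Foxa2 (148042877 to 148046969, minus) are on chromosome 2. Lmx1a (167689237 to 167848741, plus) and En1 (120602418 to 120607992, plus) are on chromosome 1. Pitx3 is on chromosome 19 (46135685 to 46148326, minus), and Slc6a3, for the dopamine transporter, on chromosome 13 (73536747 to 73578672, plus).

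At E12.5 the genes of the dopaminergic programme stood out in the ventral midbrain. Th stood at 79.1 ± 6.85 RPKM against group means of 0.683 to 4.47 in the other regions, a log2 change of 4.73 ± 0.19 (adjusted p = 1.09e-08, 3 libraries per region). Ddc, which makes dopamine from L-DOPA, reached 160.0 ± 12.2 RPKM against 1.12 to 16.3 (4.83 ± 0.48, adjusted p = 1.83e-05). The transcription factors that specify and maintain these neurons were higher as well: Lmx1a by 5.24 ± 0.68 (adjusted p = 0.000188), Foxa2 by 4.75 ± 0.62 (0.00021), En1 by 4.39 ± 0.53 (0.000114), Pitx3 by 4.33 ± 0.27 (3.56e-07) and Lmx1b by 3.48 ± 0.55 (0.00098). Slc6a3 was higher by 3.15 ± 0.21 (6.48e-07), from 0.00925 to 0.862 RPKM elsewhere to 9.56 ± 2.47. Foxa1, a partner of Foxa2 in the floor plate, was higher by 4.27 ± 0.48 (6.39e-05), and Kcnk9, a potassium channel gene, by 4.13 ± 0.36 (6.27e-06).

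Nr4a2, the nuclear receptor gene needed for dopaminergic identity, was higher by 3.42 ± 0.80 (adjusted p = 0.0139) at E12.5. This call is lost when ventral midbrain replicate 1, 2 or 3 is left out (adjusted p = 0.0661, 0.0709 and 0.0688), while the change stays at 3.43, 3.37 and 3.45.

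Among the genes lower at E12.5, Lhx2, a homeobox gene of the forebrain, was at 0.445 ± 0.139 RPKM against 4.58 to 128 elsewhere, a change of -4.85 ± 0.47 (adjusted p = 1.54e-05). Shox2, of thalamic and tectal neurons, was lower by -4.63 ± 0.34 (1.66e-06), Dbx1, of progenitors between alar and basal plate, by -4.40 ± 0.27 (3.24e-07), and Lhx9 by -4.25 ± 0.31 (1.33e-06). Barhl2, which patterns the diencephalon, was lower by -3.73 ± 0.24 (4.11e-07), Mab21l2 by -3.77 ± 0.35 and Crabp1, a retinoic acid carrier gene, by -3.73 ± 0.35. Tfap2b, of dorsal midbrain neurons, was lower by -4.31 ± 0.73 (0.00153), a call lost with voom on the recovered reads (-6.30, 0.0746). In all, 485 of 13733 genes tested were called, 375 higher and 110 lower. With voom the count was 766.

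Among the lists at E12.5, 14 of 20 floor plate genes were higher and 0 lower (14 and 0 adjusted over the list alone; camera adjusted p = 0.00787). They include Corin, a marker of the midbrain floor plate (3.92 ± 0.20, adjusted p = 6.28e-08), and Wnt1 (1.85 ± 0.14). Of 20 dopaminergic genes, 15 were higher and 0 lower (15 and 1 over the list alone; camera adjusted p = 0.00787). They include Chrna6, a nicotinic receptor subunit gene (3.25 ± 0.11, adjusted p = 2.11e-09), and Gch1, for the first enzyme of the cofactor that Th uses (2.92 ± 0.12, 1.09e-08). Of 10 motor neuron genes, 7 were higher (7 over the list alone; camera adjusted p = 0.0336, and 0.0951 without the 2 libraries of this stage that stand apart), with Slc5a7, for choline uptake (2.28 ± 0.11), and Slc18a3, for the vesicular acetylcholine transporter (2.31 ± 0.18). Of 8 serotonergic genes, 4 were higher and 0 lower (4 and 1 over the list alone, camera adjusted p = 0.0981). The 4 were Slc6a4 for the serotonin transporter (2.99 ± 0.15), Fev for a serotonergic transcription factor (2.84 ± 0.14), Tph2 for serotonin synthesis (2.19 ± 0.22) and Slc18a2 for the vesicular transporter (2.68 ± 0.44). These changes are against the mean of the other regions. The ventral hindbrain alone held more Tph2 (20.3 against 10.4 RPKM) and Slc6a4 (32.6 against 20.8) than the ventral midbrain. Fev was at 11.77 RPKM there and at 12.85 in the ventral midbrain.

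Genes of other neuron types included some that were lower at E12.5. Of 15 GABAergic genes, 8 were lower and 0 higher (9 and 0 over the list alone; camera adjusted p = 0.183), with Gad1, for GABA synthesis, at -2.18 ± 0.27 (adjusted p = 0.00012). Of 12 glutamatergic genes, 3 were lower (3 over the list alone; camera adjusted p = 0.0981). Of 12 dorsal genes, 4 were lower and 1 higher (8 and 1 over the list alone; camera adjusted p = 0.0771), and without the 2 libraries that stand apart 8 and 1 (0.0353), with Pax3 at -3.16 ± 0.35 and Pax7 at -3.13 ± 0.55. Of 18 forebrain position genes, 4 were higher and 3 lower (4 and 4 over the list alone; camera adjusted p = 0.604).

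Signalling genes moved in part at E12.5. Shh, the ventral morphogen gene, was higher by 3.75 ± 0.37 (adjusted p = 1.94e-05). Its effectors Gli3 (-2.41 ± 0.30) and Gli2 (-1.85) and the co-receptor gene Gas1 (-1.64) were lower, so that of 16 hedgehog genes 1 was higher and 5 lower (1 and 5 over the list alone; camera adjusted p = 0.604). That list's median log2 change was 0.03 while its mean was -0.22 and the test pointed down. Of 27 Wnt planar polarity genes, 5 were higher and 0 lower (5 and 0 over the list alone; camera adjusted p = 0.365), with Wnt5a at 2.94 ± 0.28 and Prickle1 at 2.03 ± 0.14. Of 33 canonical Wnt genes, 4 were higher and 3 lower (5 and 4 over the list alone; camera adjusted p = 0.604), with Lef1 at -1.51 and Tcf7l2 at -3.63. Of 37 axon guidance genes, 7 were higher and 4 lower (9 and 4 over the list alone; camera adjusted p = 0.604), with Ntn1, a floor plate attractant gene, at 3.25 ± 0.31 and Slit2, a repellent gene, at 3.16 ± 0.22. Retinoic acid genes gave 2 higher and 3 lower of 13 (2 and 3 over the list alone; camera adjusted p = 0.600), with the receptor gene Rxrg at 2.22 ± 0.19. BMP and TGF-beta genes gave 4 higher and 1 lower of 30 (4 and 1 over the list alone; camera adjusted p = 0.604), with Tgfb2, of dopaminergic neuron survival, at 1.72 ± 0.20. Notch genes gave 2 higher of 21 (2 over the list alone; camera adjusted p = 0.445), with Hey1 at 1.60.

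At E13.5 the same core genes set the ventral midbrain apart. Ddc was higher by 4.94 ± 0.22 (adjusted p = 5.9e-09), Th by 4.76 ± 0.35 (6.5e-07; 79.9 ± 17.1 RPKM against 0.640 to 3.70), Foxa2 by 4.61 ± 0.23 (1.63e-08) and Pitx3 by 4.54 ± 0.17 (8.66e-10). En1 was higher by 4.05 ± 0.26 (2.23e-07), Lmx1a by 4.0 ± 0.18 (7.35e-09), Slc6a3 by 3.49 ± 0.10 (5.15e-11), Nr4a2 by 3.24 ± 0.26 (1.31e-06) and Lmx1b by 2.58 ± 0.21 (1.45e-06). Dmrta2, which restricts other ventral midbrain fates, reached 34.5 ± 2.19 RPKM against 0.216 to 2.09 (4.30 ± 0.23, 4.03e-08), and Sulf1, which edits heparan sulfate in the matrix, was higher by 3.81 ± 0.20 (3.07e-08).

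Dbx1 had the largest decrease among named genes at E13.5, at -3.88 ± 0.37 (adjusted p = 6.66e-06; 1.29 ± 1.05 RPKM against 4.68 to 95.1). Gli3, for the repressor that opposes hedgehog signals, was lower by -1.90 ± 0.21 (3.11e-05), Crabp2, a retinoic acid carrier gene, by -1.81 ± 0.29 (0.0006) and Cntn2, an axonal adhesion gene, by -1.80 ± 0.15 (2.26e-06). In all, 334 of 13851 genes were called, 266 higher and 68 lower. Voom on the recovered reads gave 614 calls.

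Of 21 dopaminergic genes at E13.5, 16 were higher and 0 lower (16 and 0 over the list alone; camera adjusted p = 0.0017), and of 20 floor plate genes 14 were higher and 0 lower (14 and 0; camera adjusted p = 0.0104), led by Corin at 3.53 ± 0.10. Of 8 serotonergic genes 4 were higher (4 over the list alone; camera adjusted p = 0.0492): Slc6a4 at 3.41 ± 0.15, Fev at 3.33 ± 0.15, Slc18a2 at 2.95 ± 0.17 and Tph2 at 2.70 ± 0.22. Of 10 motor neuron genes 4 were higher (4 over the list alone; camera adjusted p = 0.674). Of 12 dorsal genes 5 were lower and 1 higher (6 and 1 over the list alone; camera adjusted p = 0.482).

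At E14.5 the transporter genes for dopamine were among those higher. Slc6a3 was higher by 4.08 ± 0.18 (adjusted p = 4.48e-09; 17.8 ± 0.951 RPKM against 0.0262 to 0.295) and Slc18a2 by 3.13 ± 0.31 (2.24e-05). Ddc was higher by 4.63 ± 0.38 (3.82e-06), Th by 4.62 ± 0.30 (5.37e-07), Foxa2 by 4.47 ± 0.41 (1.23e-05), Nr4a2 by 3.82 ± 0.28 (1.31e-06), En1 by 3.69 ± 0.32 (5.47e-06), Lmx1a by 3.66 ± 0.49 (0.00032), Pitx3 by 3.62 ± 0.16 (4.48e-09) and Lmx1b by 2.78 ± 0.23 (3.91e-06). Aldh1a1, the retinaldehyde dehydrogenase gene of a dopaminergic subset, was higher by 4.21 ± 0.22 (4.54e-08).

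Decreases at E14.5 included Prdm12, of sensory and spinal progenitors (-2.47 ± 0.21, adjusted p = 5.37e-06), Gli3 (-1.88 ± 0.29, 0.000904) and Sox3, of neural progenitors (-1.45 ± 0.17, 0.000138). Aurkb, a mitotic kinase gene, was at 1.51 ± 0.320 RPKM against 3.82 to 15.2 (-1.59 ± 0.33, 0.00557), a call lost with voom (-1.99, 0.0608). Of 35 cell cycle genes, 23 were lower and 0 higher (24 and 0 over the list alone; camera adjusted p = 0.415 with an estimated correlation), with Ccnd1, for cyclin D1, at -2.14 ± 0.28 (0.000236). Of 23 dopaminergic genes, 18 were higher and 0 lower (18 and 0; camera adjusted p = 0.000332), and of 19 floor plate genes 11 were higher and 1 lower (11 and 1; camera adjusted p = 0.13). Of 20 forebrain position genes, 7 were lower and 1 higher (7 and 1; camera adjusted p = 0.00894), with Nkx2-1, of the ventral forebrain, at -1.49 ± 0.16 and Dlx2, of GABAergic forebrain progenitors, at -1.25. Of 8 serotonergic genes 4 were higher (4; camera adjusted p = 0.267), with Slc6a4 at 3.40 ± 0.49 and Fev at 2.46 ± 0.39.

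In all, 460 of 14013 genes were called at E14.5, 291 higher and 169 lower. The dorsal midbrain, the only other region in the same run, gave 1618 calls alone, 1019 higher and 599 lower. Voom on the recovered reads gave 716, 622 higher and 94 lower.

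At E11.5, 3 of 13802 genes were called, all higher. Atp8a1, for a phospholipid flippase, was at 19.3 ± 1.87 RPKM against 7.09 to 9.32 (1.18 ± 0.16, adjusted p = 0.0358). The other two, chosen after their values were seen, were Ryr3, a calcium release channel gene (2.49 ± 0.275 RPKM against 0.329 to 0.695), and Clic5 (2.25 ± 1.22 against 0.0534 to 0.348). The Atp8a1 call is lost when any 1 of 8 libraries is left out (alar plate replicate 6, dorsal midbrain replicates 2, 4 and 6, ventral hindbrain replicates 2 and 6, ventral midbrain replicates 2 and 6; adjusted p = 0.0767 to 0.29). The change was 1.11 to 1.22 in those fits. A block for the replicate number also ended the call (1.18, adjusted p = 0.0982). Foxa2 stood at 3.17 ± 0.74 (adjusted p = 0.214), Th at 1.24 ± 0.58 (0.439), Lmx1a at 1.09 ± 1.0 (0.643), Nr4a2 at 0.59 ± 0.66 (0.711), En1 at 0.51 ± 0.93 (0.824) and Lmx1b at -0.90 ± 0.67 (0.58), none of them called. Pitx3 and Slc6a3 were too low to test, with Pitx3 at 0.187 RPKM and Slc6a3 listed at 0 in the ventral midbrain.

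The ventral midbrain libraries at E11.5 differ among themselves. Replicates 2, 4 and 6 held 45.9, 1.16 and 53.6 RPKM of Lmx1a, 72.1, 9.07 and 71.0 of Foxa2 and 13.2, 2.37 and 17.2 of Th. Tal2, of GABAergic midbrain precursors, ran the other way at 44.9, 163 and 46.6. Without replicate 4, 48 genes were called at E11.5, and Foxa2 was among them (4.12, adjusted p = 0.042).

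Leaving out another single E11.5 library gave 0 to 8 calls: 0 without alar plate replicate 6, without dorsal midbrain replicate 2, 4 or 6, without ventral hindbrain replicate 2 or 6, or without ventral midbrain replicate 2 or 6. It was 1 without ventral forebrain replicate 4 or ventral hindbrain replicate 4, 6 without alar plate replicate 2 and 8 without ventral forebrain replicate 2. With all 15 libraries, 1572 genes had an unadjusted p below 0.05, and voom on the recovered reads called 14. With all 60 libraries in 1 fit 172 genes were called, Foxa2 among them (3.17, adjusted p = 0.000733). That fit pools the spread over stages, with a median residual SD of 0.242 at E11.5 and 0.135 to 0.206 later, so it can understate the spread at E11.5. Without 4 libraries that stand apart, chosen after their values were seen, 128 genes were called. That set still holds alar plate replicate 2 and ventral hindbrain replicate 2, which each matched the other's region best. In the main fit of 15 libraries, 0 of 20 floor plate genes were called over all genes tested and 4 higher over the list alone (camera adjusted p = 0.719). Of 18 dopaminergic genes it was 0 and 3 higher (camera adjusted p = 0.719).

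**Figure D1:**
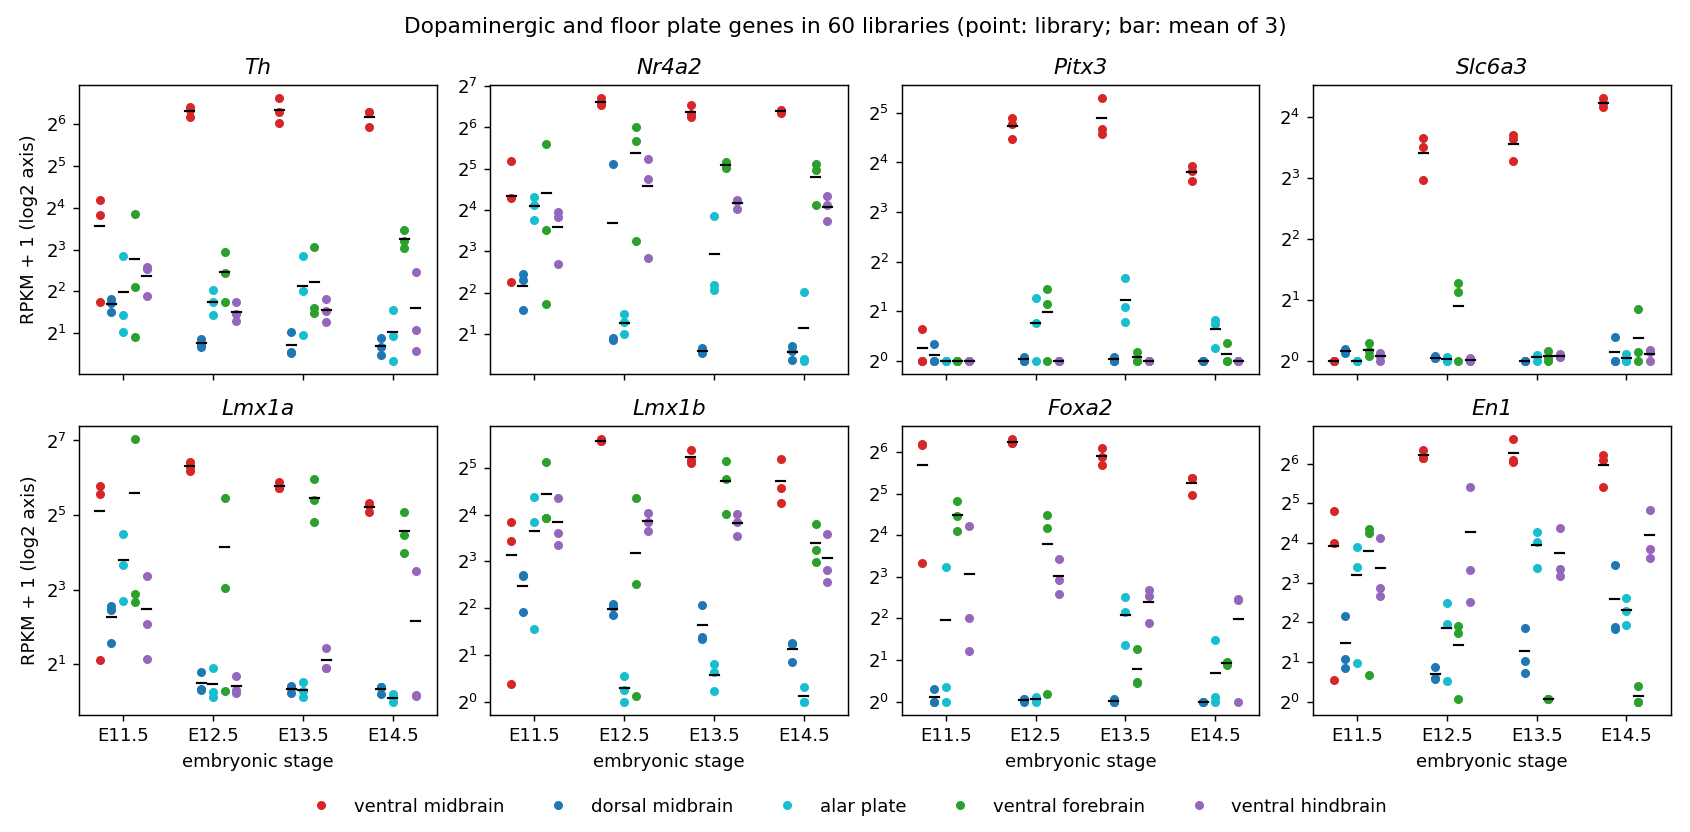
RPKM + 1 on a log2 axis for 8 dopaminergic and floor plate genes against embryonic stage, with 1 point per library coloured by region and a bar at the mean of 3 libraries. Th in the ventral midbrain goes from 10.9 RPKM at E11.5 to 79.1 at E12.5 and stays near that level, and Lmx1a in the ventral forebrain reaches 43.3 at E13.5.

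Genes called at 1 of the 3 later stages were often called at another. Between E12.5 and E13.5, 233 higher genes were shared where independent lists would share 7.25, and 52 lower genes against 0.542. Between E13.5 and E14.5 the numbers were 187 against 5.44 and 45 against 0.843, and 0 genes changed direction. Across E12.5, E13.5 and E14.5 together, 170 genes were higher and 38 lower, among them Th, Nr4a2, Pitx3, Lmx1a and Wnt5a (higher) and Dbx1, Gli3, Pax3 and Pax7 (lower).

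**Figure D2:**
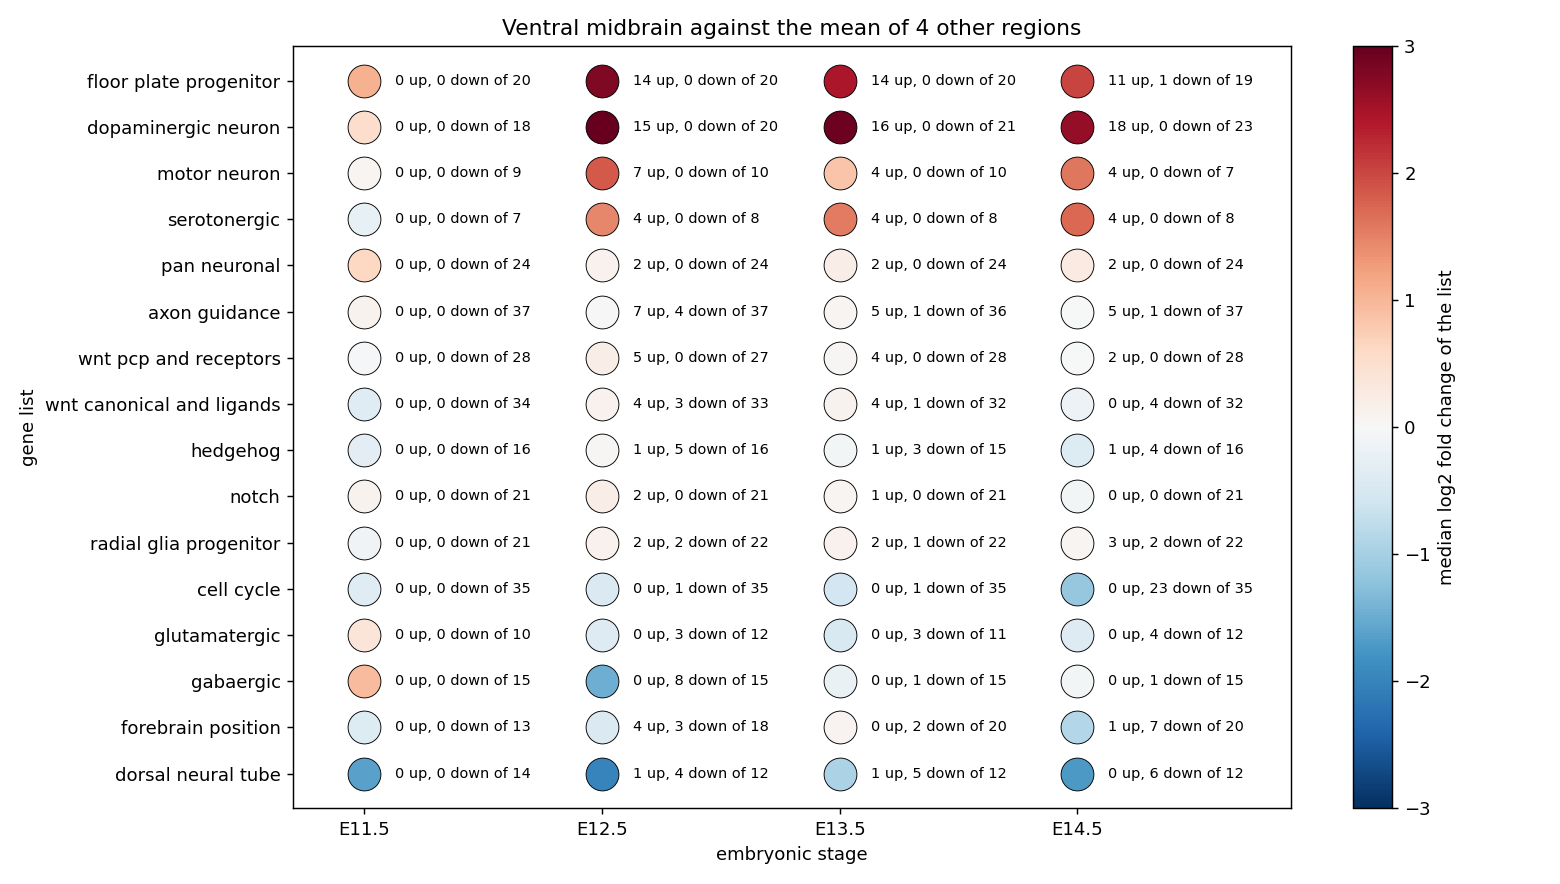
Median log2 fold change (colour) of 16 gene lists in the ventral midbrain against the mean of 4 other regions, by embryonic stage, with the numbers of members called up and down of those measured as text. The dopaminergic list has 15 of 20 members up at E12.5 and 18 of 23 at E14.5.

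Against the dorsal midbrain, averaged over the 4 stages, the genes Spon1 and Sulf1 for secreted proteins gave the largest differences among named genes. Spon1, which guides commissural axons, was higher by 6.39 ± 0.49 (adjusted p = 1.98e-14, 12 libraries per region) and Sulf1 by 6.33 ± 0.53 (3.07e-13). Foxa2 followed at 5.61 ± 0.37 (3.28e-16), with Foxa1 at 5.55 ± 0.37, Ntn1 at 5.27 ± 0.34 (2.35e-16), Ddc at 5.20 ± 0.27 (2.29e-19) and Shh at 5.12 ± 0.41 (1.01e-13). Th was higher by 4.57 ± 0.26 (6.19e-18), Lmx1a by 4.52 ± 0.45, Nr4a2 by 4.43 ± 0.38 (6.42e-13), En1 by 3.97 ± 0.39, Pitx3 by 3.36 ± 0.12, Lmx1b by 2.73 ± 0.32 and Slc6a3 by 2.70 ± 0.09 (1.47e-26). Genes that were lower include Tfap2b, by -5.41 ± 0.51 (9.29e-12), Pax3 by -4.72 ± 0.34 (4.85e-15), Lhx2 by -4.66 ± 0.50 and Zic1, of the dorsal neural tube, by -4.66 ± 0.56 (2.08e-09).

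Of 35 cell cycle genes, 33 were lower than in the dorsal midbrain and 0 higher (33 and 0 over the list alone; camera adjusted p = 0.345 with an estimated correlation). Ccnd1 was at -3.10 ± 0.22 (adjusted p = 1.47e-15), and Mcm5 and Mcm2, of DNA replication, at -1.49 and -1.38. Of 14 dorsal genes, 10 were lower (10; camera adjusted p = 0.165), and of 36 canonical Wnt genes 10 were lower and 3 higher (10 and 3; camera adjusted p = 0.615), with Lef1 at -3.04 ± 0.23 and the target gene Axin2 at -1.96. Of 23 dopaminergic genes, 17 were higher and 0 lower (17 and 0; camera adjusted p = 0.000413). Only 1 of 28 lists tested passed here, the dopaminergic list, so the floor plate list did not. Of 18 mesenchymal genes 6 were lower and 1 higher (6 and 1; camera adjusted p = 0.886), and of 8 oligodendrocyte genes 4 were higher (4; 0.165). Mitochondrial reads were 3.78 ± 0.370, 3.28 ± 0.0023, 3.70 ± 0.523 and 3.73 ± 0.139% from E11.5 to E14.5 in the ventral midbrain and 3.15 ± 0.429, 2.47 ± 0.387, 2.57 ± 0.0494 and 2.95 ± 0.517% in the dorsal midbrain. In all, 1048 of 14692 genes were called, 607 higher and 441 lower, and 2029 with voom. E12.5 and E13.5 alone gave 1289 calls, without E14.5, where both regions also shared a run.

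Against the alar plate, averaged over the 4 stages, Foxa1 and Ddc led the named genes that were higher. Foxa1 was higher by 5.03 ± 0.37 (adjusted p = 2.08e-14), Ddc by 4.86 ± 0.27 (3.17e-18), Foxa2 by 4.70 ± 0.37 (1.85e-13), Shh by 4.46 ± 0.41 (1.51e-11), Lmx1a by 4.25 ± 0.45 and Th by 3.92 ± 0.26 (1.32e-15). Nr4a2 (3.59 ± 0.38), Lmx1b (3.46 ± 0.32), Pitx3 (2.78 ± 0.12), Slc6a3 (2.76 ± 0.09) and En1 (2.73 ± 0.39) were higher too. Tfap2b was lower by -5.08 ± 0.51 (1.59e-10), Lhx9 by -4.22 ± 0.39 (1.9e-11), Pax3 by -3.19 ± 0.34, Pax7 by -2.69 ± 0.35 and Fgf15, of neural progenitors, by -2.64 ± 0.39 (8.92e-07).

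Of 20 floor plate genes, 15 were higher than in the alar plate and 0 lower (15 and 0 over the list alone; camera adjusted p = 0.00526), and of 23 dopaminergic genes 16 and 0 (16 and 0; camera adjusted p = 1.99e-06). Of 14 dorsal genes 10 were lower and 1 higher (10 and 1; camera adjusted p = 0.124). In all, 389 genes were called, 292 higher and 97 lower, and 823 with voom. E12.5 and E13.5 alone gave 572.

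Against the ventral forebrain, averaged over the 4 stages, the midbrain position genes En2 and En1 gave the largest differences among named genes. En2 was higher by 4.48 ± 0.52 (adjusted p = 1.37e-08, 12 libraries per region) and En1, which also keeps midbrain neurons alive, by 4.24 ± 0.39 (4.14e-11). Foxa2 was higher by 3.39 ± 0.37 (3.22e-09), Ddc by 3.30 ± 0.27 (1.51e-12), Pitx3 by 3.14 ± 0.12, Th by 3.03 ± 0.26 (6.22e-12), Corin by 2.94 ± 0.40 (3.99e-07) and Slc6a3 by 2.45 ± 0.09. Nkx2-1, which specifies the ventral forebrain, was lower by -3.53 ± 0.34 (1.47e-10), Dbx1 by -3.85 ± 0.45 (1.5e-08) and Lhx6, of migrating interneurons, by -1.49 ± 0.12 (2.89e-13).

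Lmx1a and Lmx1b, which are also active in the posterior ventral forebrain, were not called against that region over all 4 stages. Without the E11.5 libraries both are called (Lmx1a 1.49, adjusted p = 0.00472; Lmx1b 1.72, 1.85e-05), as they are in E12.5 and E13.5 alone (1.88, 0.00539; 1.92, 0.000927). Lmx1a was at 1.10 ± 0.45 (adjusted p = 0.106) and is called without ventral forebrain E11.5 replicate 2 (1.46, 0.0164), ventral midbrain E11.5 replicate 4 (1.48, 0.00967) or ventral forebrain E12.5 replicate 3 (1.42, 0.0209). Lmx1b was at 0.85 ± 0.32 (0.0698) and is called without ventral midbrain E11.5 replicate 4 (1.12, 0.00417) or ventral forebrain E12.5 replicate 3 (1.10, 0.00671). Nr4a2 was higher by 1.22 ± 0.38 (0.0273), a call lost without ventral forebrain E11.5 replicate 6 (0.98, 0.0681), ventral midbrain E11.5 replicate 6 (1.06, 0.0711) or ventral forebrain E12.5 replicate 1 (1.0, 0.0871). That call is also lost without the 6 libraries that stand apart (0.71, 0.172), in E12.5 and E13.5 alone (1.46, 0.0744) and with a pseudocount of 0.1 (1.26, 0.0606).

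Of 21 forebrain position genes, 13 were lower than in the ventral forebrain and 0 higher (14 and 0 over the list alone; camera adjusted p = 0.000908), with Dlx1 at -2.50 and Dlx2 at -1.98. Of 23 dopaminergic genes 16 were higher and 1 lower (16 and 1; camera adjusted p = 9.37e-09), of 20 floor plate genes 10 and 0 (11 and 0; 0.0174), of 10 motor neuron genes 4 and 0 (4 and 0; 0.0174) and of 8 serotonergic genes 5 and 0 (6 and 0; 0.0147). In all, 220 genes were called, 162 higher and 58 lower, and 423 with voom. E12.5 and E13.5 alone gave 430 and the 3 stages without E11.5 gave 369.

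Against the ventral hindbrain, averaged over the 4 stages, Dmrta2 was higher by 4.32 ± 0.42 (adjusted p = 1.59e-10), Emx2 by 3.72 ± 0.38 (6.1e-10) and Otx2, which marks forebrain and midbrain, by 3.33 ± 0.36 (2.11e-09). Lmx1a was higher by 4.12 ± 0.45 (3.66e-09), Th by 3.84 ± 0.26 (4.2e-15), Pitx3 by 3.40 ± 0.12, Foxa2 by 3.29 ± 0.37, Slc6a3 by 2.72 ± 0.09, Nr4a2 by 1.83 ± 0.38 (0.000724) and En1 by 1.70 ± 0.39 (0.00235). Lmx1b, which serotonergic neurons also need, was at 0.90 ± 0.32 (0.0629) and is called without ventral midbrain E11.5 replicate 4 (1.17, 0.00277), without all E11.5 libraries (1.61, 8.61e-05) and in E12.5 and E13.5 alone (1.58, 0.00788). Cyp26b1, which breaks down retinoic acid, was lower by -4.14 ± 0.40 (1.59e-10), Otp, of hypothalamic and hindbrain neurons, by -3.83 ± 0.38 (3.37e-10), Meis2 by -3.30 ± 0.38 (7.98e-09) and the hindbrain segment gene Hoxa2 by -2.92 ± 0.36 (5.01e-08).

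Of 9 hindbrain position genes, 5 were lower than in the ventral hindbrain and 0 higher (6 and 0 over the list alone; camera adjusted p = 0.145), with Hoxb2 at -2.44 and Hoxb3 at -1.72. Of 23 dopaminergic genes 14 were higher and 0 lower (14 and 0; camera adjusted p = 3.67e-08) and of 20 floor plate genes 12 and 0 (13 and 0; 0.000481). Of 8 serotonergic genes 1 was higher and 0 lower (1 and 0; 0.955), Slc18a2, which dopaminergic neurons share (1.22 ± 0.22). In all, 215 genes were called, 120 higher and 95 lower, and 406 with voom. E12.5 and E13.5 alone gave 320.

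The genes higher in the ventral midbrain than in each of the 4 other regions, averaged over the 4 stages, number 51. At E11.5 alone, against the mean of the other regions, each of them was either not called or not tested. Ddc led with a smallest difference of 3.30, followed by Foxa2 (3.29), Th (3.03), Pitx3 (2.78), Chrna6 (2.76), Dmrta2 (2.62), Slc6a3 (2.45), the neuropeptide gene Cartpt (2.33), Kcnk9 (2.02) and Aldh1a1 (1.73). En1 and Wnt5a (both 1.70), Ret, the GDNF receptor gene (1.43), Gch1 (1.36), Slit2 (1.29), Shh (1.22) and Slc18a2 (1.22) were also among them. Only Dbx1 (smallest difference 1.63), Crabp2 (1.07) and Gli3 (1.02) were lower than in each region.

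The 4 comparisons behind these 51 genes use the same ventral midbrain libraries. In 10 simulated draws with no effect that share them in the same way, at most 0 genes passed all 4. At most 0 were called in any of the 4 in those draws, so they cannot show whether sharing adds genes. E12.5 and E13.5 alone gave 89 genes, and voom on the recovered reads gave 97.

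From E11.5 to E14.5 in the ventral midbrain, genes of dopaminergic neurons were among those that rose and genes of dividing cells among those that fell. Slc6a3 rose by 4.23 ± 0.17 (adjusted p = 2.09e-08; listed at 0 at E11.5), Pitx3 by 3.58 ± 0.21 (1.21e-07), Th by 2.92 ± 0.47 (0.000191), En1 by 2.80 ± 0.79 (0.00918) and Nr4a2 by 2.47 ± 0.51 (0.00127). Lmx1b rose by 2.12 ± 0.66 (0.0159), a call lost without ventral midbrain E14.5 replicate 3 (1.86, 0.0572). Lmx1a (1.07 ± 0.89, 0.322) and Foxa2 (0.01 ± 0.57, 0.989) were not called. Pcp4, a calmodulin regulator gene, rose by 4.50 ± 0.26 (1.01e-07; 1.27 to 51.9 ± 17.1 RPKM), Chrna6 by 4.47 ± 0.21, the calcium buffer gene Calb2 by 4.32 ± 0.55, Aldoc by 4.31 ± 0.25 and Slc6a4 by 4.25 ± 0.37 (1.42e-06).

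Without ventral midbrain E11.5 replicate 4, Foxa2 was at -0.94 (adjusted p = 9.86e-05) and Lmx1a at -0.44 (0.00303), both short of the fold minimum. The embryonic globin genes gave the largest decreases among named genes: Hbb-bh1 by -8.34 ± 0.51 (adjusted p = 1.31e-07; 516.5 ± 338 to 0.563 ± 0.976 RPKM) and Hba-x by -5.32 ± 0.29 (7.89e-08). Top2a, which untangles DNA in dividing cells, went from 110.4 ± 17.7 to 7.34 ± 1.76 RPKM (-3.75 ± 0.20, 5.85e-08), and Rrm2 (-3.68 ± 0.19), Ccnb1 (-3.56 ± 0.17) and Crabp2 (-4.44 ± 0.25) fell with it.

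All 35 cell cycle genes fell from E11.5 to E14.5 (35 over the list alone; camera adjusted p = 0.31 with an estimated correlation), with Mcm2 at -3.09 ± 0.12. Of 23 dopaminergic genes 17 rose and 1 fell (17 and 1; camera adjusted p = 0.31), of 24 general neuronal genes 11 rose and 0 fell (11 and 0; 0.31), with Mapt, for tau, at 2.37 ± 0.11, and of 21 Notch genes 2 rose and 9 fell (2 and 9; 0.31), with the target gene Hes5 at -2.54. Of 10 erythroid genes 4 rose and 6 fell (4 and 6; 0.887). In all, 2468 of 13868 genes were called, 1440 higher and 1028 lower. Stage and run change together here and cannot be told apart.

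The change from E11.5 to E14.5 in the ventral midbrain differed from that in the other regions for 134 of 14590 genes, 95 with a higher and 39 with a lower change. Slc6a3 differed by 4.18 ± 0.19 (adjusted p = 2.85e-13) and Pitx3 by 3.43 ± 0.20 (3.78e-11). Slc6a4 differed by 4.39 ± 0.76 (0.0038; 0.120 to 22.6 RPKM in the ventral midbrain, 2.09 to 4.78 elsewhere), a call lost with voom (8.0, 0.162). The mean elsewhere includes the ventral hindbrain, which alone held 18.9 RPKM of Slc6a4 at E14.5 (2.44 to 29.7 over its libraries). The Slc6a4 rise is therefore not shown to be particular to the ventral midbrain, and the change in the ventral hindbrain alone was not tested. Cd9, a tetraspanin gene, had a difference of 1.81 ± 0.33 (0.00607; 4.69 to 19.2 against 9.64 to 10.3 RPKM). Dmbx1, of midbrain progenitors, had a difference of -3.13 ± 0.56 (0.00562), lost with voom (-5.69, 0.112), and Islr2, of axon growth, of -2.85 ± 0.57 (0.0101), lost without the dorsal midbrain (-2.74, 0.0771). Lmx1a (2.57 ± 1.18, 0.298) and Foxa2 (1.30 ± 0.90, 0.519) were not called, nor was En1 (3.18 ± 1.03, 0.131), which is called without ventral forebrain E11.5 replicate 2 (3.49, 0.0404).

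Th differed by 3.38 ± 0.69 (adjusted p = 0.0115; 10.9 ± 7.69 to 71.9 ± 9.70 RPKM against 3.81 to 3.05), a call lost without ventral midbrain E11.5 replicate 4 (2.63, 0.0579) or without the dorsal midbrain (3.20, 0.0863). Lmx1b differed by 3.67 ± 0.74 (0.0102), lost without ventral midbrain E14.5 replicate 3 (3.42, 0.0534) or without the dorsal midbrain (3.75, 0.0533). Of 23 dopaminergic genes, 11 had a higher change and 0 a lower one (16 and 0 over the list alone; camera adjusted p = 2.83e-05), with Chrna6 at 4.44 ± 0.17. Of 8 serotonergic genes 4 had a higher change (5 over the list alone; camera adjusted p = 0.267), with Tph2 at 3.80 ± 0.84 and Fev at 3.25 ± 0.73, and of 20 forebrain genes 5 a lower one (6; camera adjusted p = 0.0777), or 3 without the libraries that stand apart (0.00265).

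The 134 genes become 86 without ventral midbrain E11.5 replicate 2, 88 without replicate 6 of that group, 75 without ventral midbrain E14.5 replicate 3 and 84 without replicate 4 of that group. Without the dorsal midbrain, whose E11.5 libraries are in another run, 47 genes were called, and voom on the recovered reads gave 59; no other region shares the run of the ventral midbrain at both stages, so there is no value within a run.

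The libraries of E11.5 stand apart from those of the later stages in how well they match their labelled region. With the region profiles of E12.5, E13.5 and E14.5 in turn, 7, 8 and 9 of the 15 E11.5 libraries correlated best with their own region, where 3 would by chance. Alar plate E11.5 replicate 2 matched the ventral hindbrain best with each of the 3 profiles (0.614, 0.551 and 0.469), and ventral hindbrain E11.5 replicate 2 the alar plate (0.472, 0.367 and 0.402). Both are kept as labelled in the averages against those regions. Ventral forebrain replicates 4 and 6 held 18.2 and 19.6 RPKM of En1, a midbrain and anterior hindbrain gene, with Nkx2-1 listed at 0, while replicate 2 held 0.584 of En1 and 30.8 of Nkx2-1.

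**Figure D3:**
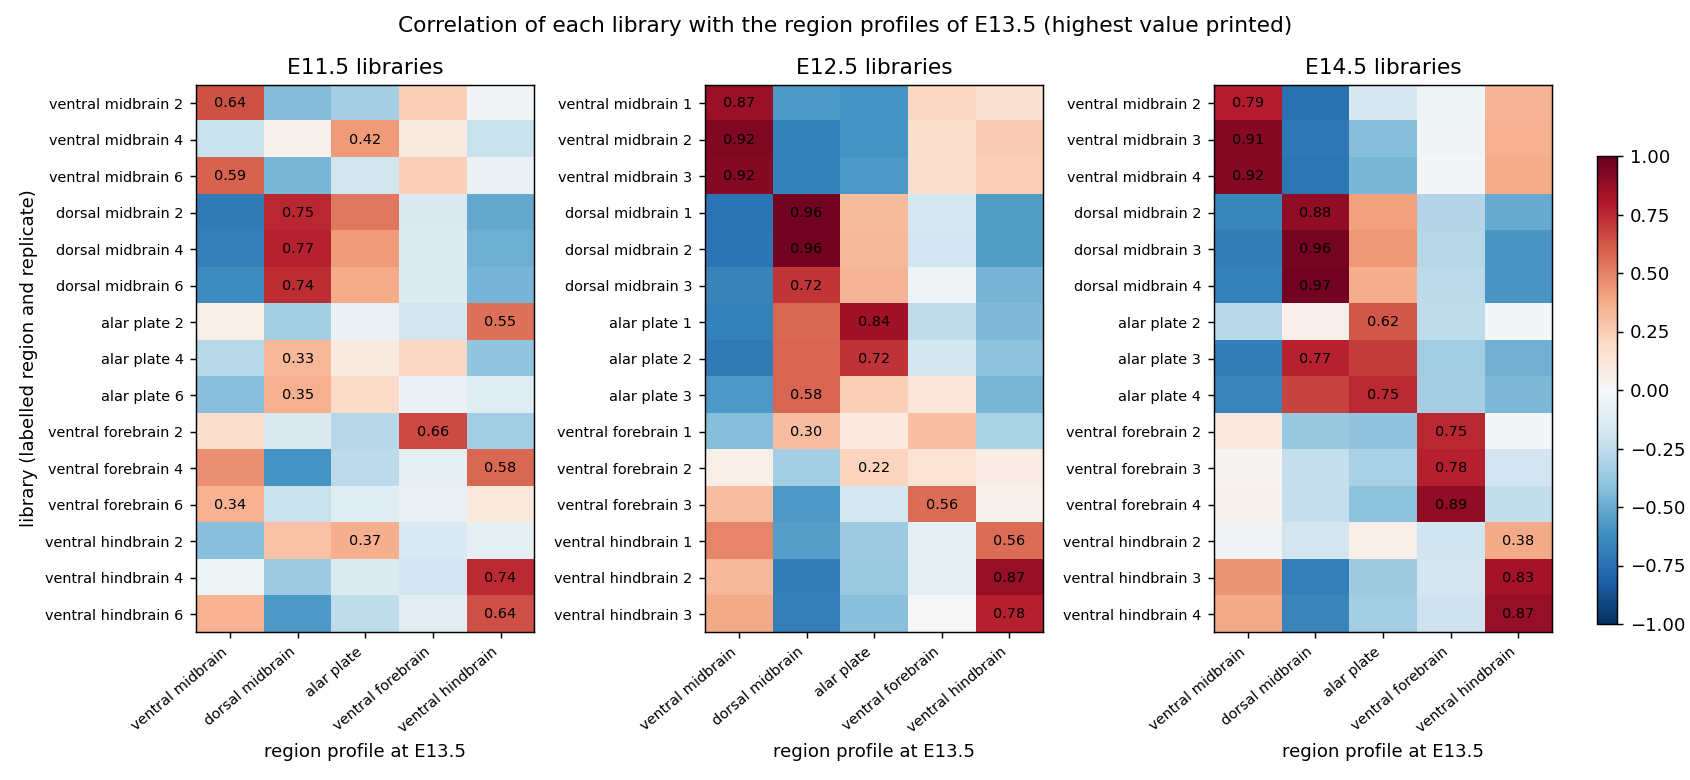
Correlation (colour) of each E11.5, E12.5 and E14.5 library with the 5 region profiles of E13.5, libraries on the vertical axis and profiles on the horizontal axis, the highest value of each library printed. At E11.5, 8 of 15 libraries match their own region best.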

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

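Of the tests in this part, the test of dopaminergic neurons sharing members of the serotonergic list, voom and leaving out 6 libraries were chosen after seeing the result.

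The change from E11.5 to E14.5 differed between the ventral midbrain and the other regions for 134 genes, by the interaction term. The differences among named genes were Slc6a4 4.39, Slc6a3 4.18, Lmx1b 3.67, Pitx3 3.43, Th 3.38, Nr4a2 3.23, Slc18a2 2.37, Sparcl1 2.23 and Cd9 1.81 on the log2 scale. Lower changes were Tal2 -3.97, Dmbx1 -3.13, Islr2 -2.85, Lef1 -2.61, Cbln2 -2.27, Foxb1 -2.25 and Hist1h4i -1.95. Lef1, of Wnt signalling, went from 9.08 to 1.85 RPKM in the ventral midbrain and from 10.7 to 26.8 elsewhere. Tal2 went from 84.8 ± 67.6 (44.9, 163 and 46.6 in replicates 2, 4 and 6) to 5.79 ± 0.663 in the ventral midbrain. Elsewhere it went from 24 ± 32.8 to 60.5 ± 76.6. The SD elsewhere is over all libraries of the 4 other regions at a stage, so it includes differences between regions. The Tal2 call is lost without the 6 libraries that stand apart (-3.72, adjusted p = 0.0822).

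Several of these calls lie near the threshold and are lost when 1 library is left out. The Cbln2 call is lost with any of 20 libraries (-2.49 to -1.99, adjusted p = 0.0505 to 0.157), that of Lef1 with any of 11 (-2.86 to -2.26, 0.0506 to 0.145) and that of Tal2 with any of 10 (-4.29 to -3.37, 0.0519 to 0.148). The call of Nr4a2 (2.41 to 3.42, 0.0595 to 0.151) is lost with any of 5 ventral midbrain libraries, and those of Foxb1 (-2.15 to -2.02, 0.0503 to 0.065) and Hist1h4i (-1.78 to -1.66, 0.0922 to 0.103) with any of 3. The Sparcl1 call is lost without ventral midbrain E11.5 replicate 2 (2.10, 0.0598) or E14.5 replicate 3 (2.16, 0.0593).

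Without the dorsal midbrain, the calls of Nr4a2 (2.96, adjusted p = 0.175), Slc18a2 (2.13, 0.0863), Tal2 (-3.72, 0.175), Lef1 (-2.47, 0.175), Cbln2 (-2.08, 0.209) and Hist1h4i (-1.94, 0.0812) are lost, as are those of Th (3.20, 0.0863), Lmx1b (3.75, 0.0533) and Islr2 (-2.74, 0.0771). With voom on the recovered reads, those of Slc6a4 (8.0, 0.162), Dmbx1 (-5.69, 0.112), Tal2 (-4.11, 0.192), Lef1 (-3.29, 0.175), Foxb1 (-2.40, 0.224), Hist1h4i (-2.26, 0.162) and Cbln2 (-2.20, 0.0969) are lost. The calls of Slc6a3 and Pitx3 are kept in both. A block for the replicate number ends those of Lef1 (-2.61, 0.0572), Tal2 (-3.97, 0.0671) and Cbln2 (-2.27, 0.0764).

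When region labels were drawn again within the stages, 3 of 100 splits, the real one included, gave at least 134 genes. The highest other count was 262, for the 3 dorsal midbrain libraries of E14.5 put in place of the ventral midbrain, which share its run. The runs of E11.5 and E14.5 differ in each region, and not in the same way, so for the count of genes the difference cannot be told apart from run. A run effect shared by all libraries of a run would not give the values of Slc6a3 and Pitx3: within the run of E14.5, Slc6a3 was at 17.8 ± 0.951 RPKM in the ventral midbrain and 0.103 ± 0.178 in the dorsal midbrain, and Pitx3 at 12.9 ± 1.41 and listed at 0. At E11.5, in the run that the ventral midbrain shared with 3 regions, Slc6a3 was listed at 0 in the ventral midbrain and at 0 to 0.127 in those regions.

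Of 8 serotonergic genes, 4 were higher in the ventral midbrain than the mean of the other regions at each of E12.5, E13.5 and E14.5 (camera adjusted p = 0.0981, 0.0492 and 0.267), and 1 of 8 was higher than in the ventral hindbrain (0.955). A candidate explanation is tissue like the ventral hindbrain libraries in the dissected pieces, which would put the ventral midbrain lower. Means in ventral midbrain and ventral hindbrain were 16.6 ± 4.37 and 7.12 ± 2.23 RPKM for Fev, 11.7 ± 3.18 and 8.61 ± 4.51 for Tph2 and 22.6 ± 6.93 and 14.9 ± 3.72 for Slc6a4 at E13.5, and 7.73 ± 2.90 and 5.49 ± 4.31, 13.6 ± 7.36 and 12.6 ± 9.23, and 22.6 ± 11.4 and 18.9 ± 14.51 at E14.5 in that order of genes. All 6 lay higher, but at E12.5 Tph2 (10.4 against 20.3) and Slc6a4 (20.8 against 32.6) lay lower, and only 1 of 6 pairs at E13.5 and E14.5 had all ventral midbrain libraries above all ventral hindbrain libraries, which leaves that explanation open. Members shared with dopaminergic neurons do not account for it, since 3 members outside that overlap were called at both E13.5 and E14.5, and no biological explanation was tested beyond that.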

How the results depend on the processing

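The settings added after seeing the data are voom on the recovered reads, leaving out 6 libraries that stand apart, and leaving out E11.5; the others were fixed before. The cause was not tested for any change given here unless stated.

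Median centring kept the call and direction of all 195 values that the rule for named genes selects, and without the filter 193 of 195 kept theirs. With a pseudocount of 0.1, 189 of 195 did. The count of called genes then went from 3 to 0 at E11.5, from 334 to 613 at E13.5, from 460 to 766 at E14.5, from 1048 to 1946 against the dorsal midbrain, from 389 to 796 against the alar plate, from 220 to 451 against the ventral forebrain and from 215 to 410 against the ventral hindbrain. Genes higher than in each region went from 51 to 90 and the difference in change over time from 134 to 78. Low values gain fold by construction there, which alone does not account for the counts that fell.

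Without a fold minimum, which adds genes by construction, the counts were 1484 at E12.5, 3046 at E13.5, 2533 at E14.5, 8500 against the dorsal midbrain, 4681 against the alar plate, 1833 against the ventral forebrain, 1347 against the ventral hindbrain, 310 against each region and 8377 from E11.5 to E14.5. Voom on the recovered reads gave 14 at E11.5, 766 at E12.5, 614 at E13.5, 716 at E14.5, 2029, 823, 423 and 406 against the 4 regions in the same order, 97 against each region and 59 for the difference in change over time. With voom, 177 of 195 named values kept their call and En1 at E11.5 reversed to -0.51.

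With a block for the replicate number 168 of 172 named values kept their call, and the count at E11.5 was 0. The calls lost were Atp8a1 at E11.5 (1.18, adjusted p = 0.0982) and, in the difference in change over time, Lef1 (-2.61, 0.0572), Tal2 (-3.97, 0.0671) and Cbln2 (-2.27, 0.0764). The block cannot be fitted to E14.5 against E11.5. The labels do not say that a number marks 1 embryo. As a hint, 42 of 60 libraries correlated best with their own number (20 expected), 61 of 120 pairs of the same number correlated above 0.1 (median 0.112, against -0.058 for other pairs), and each of 12 numbers was of 1 sex in all 5 regions (exact p = 1.88e-06). That p rests on the 3 stages with both sexes, since all E11.5 libraries were female. The correlations give no such hint at E11.5 (median 0.002 against -0.012, 10 of 30 pairs above 0.1).

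Without the 6 libraries that stand apart, 150 of 155 named values kept their call. E11.5 rose to 128 calls, and in the ventral midbrain from E11.5 to E14.5 Lmx1a reversed to -0.44 and Foxa2 to -0.94. All 60 libraries in 1 fit, with the spread pooled over stages, gave 172 at E11.5. Leaving out E11.5 gave 369 against the ventral forebrain. Within shared runs, with that of E12.5 assumed, E12.5 and E13.5 alone gave 430 against the ventral forebrain and 89 against each region. E14.5 against the dorsal midbrain alone gave 1618. Leaving out the dorsal midbrain gave 0 at E11.5 and 47 for the difference in change over time. With the preset correlation, 88 list tests passed in place of 19.

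Leaving out 1 library at a time kept 3702 of 3798 named values. Counts ranged from 0 to 48 at E11.5 (48 without ventral midbrain replicate 4) and from 75 to 188 for the difference in change over time. They ranged from 410 to 512 at E12.5, 302 to 363 at E13.5, 338 to 521 at E14.5, 1001 to 1146, 366 to 441, 193 to 251 and 196 to 259 against the 4 regions, 44 to 69 against each region and 2380 to 2591 from E11.5 to E14.5. At E11.5, Nr4a2 ranged from -0.04 to 1.41, Lmx1b from -1.54 to 0.19 and En1 from -0.34 to 1.80. From E11.5 to E14.5 in the ventral midbrain, Foxa2 ranged from -0.94 to 0.49 and Lmx1a from -0.44 to 1.89; Foxa2 was at -0.06 without E14.5 replicate 3 or 4.

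Totals were lowest at E11.5 and E14.5, so genes at low values rest on few reads there. Thinning E12.5 to the E11.5 depths did not lower its count (494 to 500 calls against 485). The depth of E14.5 was not tested.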

Other observations

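Of the tests in this part, those of exchanged labels and of the depth of the ventral forebrain libraries were chosen after seeing the result, as was the choice of the libraries that stand apart.

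At E12.5 some genes outside the neuronal and signalling groups were also higher in the ventral midbrain. Lhx4, a homeobox gene of motor neurons and pituitary, was higher by 3.29 ± 0.10 (adjusted p = 6.65e-10), Folr1, a folate receptor gene, by 2.58 ± 0.21 (4.96e-06) and Postn, a matrix gene, by 2.22 ± 0.59 (0.0282). Lhx4 is the 1 of 3 measured pituitary genes called (1 over the list alone), with a list median of -0.12 and a mean of 0.92, and Folr1 the 1 of 4 choroid plexus genes (1 over the list alone); both lists were too small to test. Of 36 extracellular matrix genes 3 were higher and 2 lower (4 and 2 over the list alone; camera adjusted p = 0.604), and of 22 radial glia genes 2 and 2 (2 and 2; 0.604), with Slc1a3, a glial glutamate transporter gene, at 1.86. Of 24 general neuronal genes 2 were higher (2; 0.604), the neurofilament genes Nefm at 1.81 and Nefl at 1.96.

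Markers of other cells moved little at E12.5. Of 17 mesenchymal genes 1 was higher and 1 lower (1 and 4 over the list alone; camera adjusted p = 0.604), and 0 members were called of 9 erythroid (0.604), 14 endothelial (0.676), 12 microglial (0.604), 6 oligodendrocyte (0.765) and 10 stress genes (0.805), nor over those lists alone. The oligodendrocyte list had a median of 0.15 and a mean of -0.06, and the stress list 0.04 and -0.02. Haemoglobin reads were 0.229 to 2.52% of a library at E11.5, 0.193 to 0.562% at E12.5, 0.224 to 0.441% at E13.5 and 0.131 to 0.404% at E14.5.

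By the Y-linked gene Ddx3y and by Xist, 4 of the 12 stage and replicate numbers were male (E12.5 replicate 3, E13.5 replicates 4 and 6, E14.5 replicate 2) and 8 female. All E11.5 libraries were female.

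Few genes were called at E11.5. Depth is not a fit for this: E12.5 libraries thinned to the E11.5 depths still gave a median of 496 calls (494 to 500). Libraries that stand apart from their groups may explain much of it, since 128 genes were called without the 4 of them at E11.5, though these were chosen after seeing marker values and their removal lowers the spread in part by construction. Smaller regional differences at this stage remain open as the biological explanation. The median log2 change at E11.5 for genes called higher at the 3 later stages was 0.99 without those libraries and 0.44 with all 15. Neither value decides anything, since these genes were chosen for a change of at least 1 at the other stages.

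Ventral forebrain E11.5 replicates 4 and 6 held En1 and no Nkx2-1, and depth does not explain the missing gene, since at the level of replicate 2 at least 228 reads of Nkx2-1 would be expected in each. A swap with ventral midbrain replicate 4 could account for only 1 of the 2 libraries and remains open for it. With the E12.5 profiles, ventral midbrain replicate 4 matched the ventral forebrain best (0.582, a gap of 0). With the E13.5 and E14.5 profiles it matched the alar plate best (0.425 and 0.447), with gaps of 0.339 and 0.486 to the ventral forebrain. Its correlation with its own region was -0.396, -0.219 and -0.214 with the E12.5, E13.5 and E14.5 profiles. With the E12.5 profiles, ventral forebrain replicates 2 and 6 matched the ventral midbrain best (0.300 and 0.369) and replicate 4 the ventral hindbrain (0.767). With the E13.5 and E14.5 profiles replicate 2 matched the ventral forebrain best (0.657 and 0.489), replicate 6 the ventral midbrain (0.345 and 0.271) and replicate 4 the ventral hindbrain (0.577 and 0.617). Exchanged labels remain open too. The least matched region was the best match of 1 library with the E12.5 and E13.5 profiles, rather than 3. With the E14.5 profiles it was the best match of 2. Libraries of the 3 later stages, matched to each other's profiles, gave 1 to 3, so this count cannot decide the question. Tissue from another position along the neural tube also remains open: 46.2% of 13 forebrain genes were lower in both libraries than in replicate 2 (95% exact interval 19.2 to 74.9), where 33.3% would be by chance. That interval treats genes measured in the same libraries as independent. Gsx1, Hmx2 and Hmx3 were listed at 0 in replicate 2, so they could not be lower in replicates 4 and 6. The chance share does not hold for those genes, and the test cannot decide the question. No biological explanation was tested.

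When region labels were drawn again, the real split included, 7 of 100 splits at E11.5 gave at least the real 3 calls and the highest other count was 412, so chance is not excluded there. That split put alar plate replicate 4 with ventral forebrain replicates 2 and 6. At E12.5 it was 1 of 100 (highest other count 234), at E13.5 3 of 100 (1042, the 3 dorsal midbrain libraries) and at E14.5 3 of 100 (550). Against single regions it was 1 of 100 each for the dorsal midbrain (375), alar plate (82), ventral forebrain (89) and ventral hindbrain (52), and 1 of 100 for genes higher than in each region (2). For E14.5 against E11.5 in the ventral midbrain there are only 10 splits, too few to tell; the real one was the largest (1 of 10; highest other count 2).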
